A study of Mus musculus with 6 samples.

How the data were processed

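Small RNA was sequenced from isolated urinary bladder cells of mice given cyclophosphamide, an alkylating cytotoxic drug whose urinary breakdown products injure the bladder, and of mice given saline. Per the labels, the CYP group received 4 intraperitoneal injections of 80 mg/kg on days 2, 4, 6 and 8, and the libraries were made from 100 ng of total RNA with a Qiagen miRNA library kit. The labels give an age of 8 weeks for both groups and a time of 8 days after induction for the CYP group. There were 3 Control and 3 CYP libraries. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

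The deposited tables give whole-number counts of reads and of unique molecular identifiers (UMIs, random tags that mark single cDNA molecules) per miRNA, piRNA, tRNA, other RNA and uncharacterized mappable sequence, not normalized, per the file headers. A summary table deposited by the authors gives read counts per class of RNA in each library. Per the submitters' processing notes, FastQC 0.11.7, Trim Galore, STAR 2.6 and DESeq2 were used with the mm10 genome build. What each tool did and the counting tool are not given in the sources used here. The deposited fold table holds fold changes (a ratio of CYP to Control) and unadjusted p-values, both computed by the authors with DESeq2, per the file headers. In that table, 51 of the 1451 p-values are missing. Every feature in the count tables reaches at least 10 UMIs in 1 library, so features below that level were not analysed here. How the authors' counting split reads between near-identical mature sequences is not given in the sources used here, so such features are reported as uncertain.

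UMI counts were tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood test on the group term with trimmed-mean (TMM) scaling. Each class was tested on its own counts and its own library totals. Features were kept by edgeR's default filter (a minimum count of 10 and a minimum total count of 15). P-values were adjusted by the Benjamini-Hochberg method within a class, and an adjusted p below 0.05 was taken as a call. Levels are given in CPM, UMI counts of a class scaled to the same total in each library, as mean ± SD over the 3 libraries of a group, and fold changes as log2 values ± SE from edgeR. The table of miRNAs holds between 9110719 and 12180739 UMIs per library, with 1.07 to 1.10 reads per UMI. The totals run from 30337 to 55920 UMIs for piRNAs, from 596152 to 2212083 for tRNA features and from 817756 to 1617505 for other RNA.

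Lists of miRNAs were tested with camera from limma 3.58.1 on voom values, with a preset correlation of 0.01, adjusted over the 21 lists with at least 3 tested members. Camera asks whether a list's members differ from the other miRNAs. The same test with an estimated correlation, and fry, which asks whether the members move one way on balance, were run beside it. The 23 lists were the study-named miRNAs, the miR-34 and miR-449 family, p53-linked miRNAs, miR-21, the miR-132 and miR-212 cluster, the Dlk1-Dio3 cluster, inflammation-induced miRNAs, epithelial miRNAs, smooth and striated muscle miRNAs, fibroblast miRNAs, the miR-29 family, leukocyte, myeloid and lymphoid miRNAs, erythroid miRNAs, endothelial, neuronal, and liver and kidney miRNAs, proliferation clusters, the miR-15/16 family, the miR-143 and miR-145 cluster, the let-7 family and miR-210. Shares of reads per class were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1. Fold changes were set beside the authors' deposited table as a description, since both come from the same libraries.

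The groups, the tests, the lists, the alternatives and the rule for named features were fixed before the data were examined, except where the text says otherwise. By that rule the text names up to 12 miRNAs in each direction with the largest fold change among those called, with a mean of at least 10 CPM and no overlap between the groups. It also names the 8 miRNAs in the study's design text, the 10 most abundant miRNAs, 2 to 4 members of each list with the smallest p, and up to 5 features in each direction for piRNA, tRNA and other RNA. Hairpin positions are those of the GENCODE M21 annotation of mm10, which gave a position for 1238 of the 1277 miRNAs. It also matched 1046 of the 1079 transcript identifiers in the tables of tRNA and other RNA. Tests of genomic clusters of hairpins lying within 10 kb of each other, and of the uncharacterized sequences, were added after the data were seen.

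The edgeR script was tested on simulated counts drawn from the real means and library sizes. With 200 of 885 simulated miRNAs changed, it recovered 38.8% of those changed 1.5-fold, 76.1% of those changed 2-fold and 86.4% of those changed 4-fold, and 1.47% of its calls were false, with the right sign for all that were recovered. For 165 simulated piRNAs the shares at 1.5, 2 and 4-fold were 14.3%, 42.9% and 84.6%. For 369 simulated tRNA features they were 16.1%, 58.1% and 100%, and for 679 simulated other RNA features 22.8%, 50.0% and 89.3%. For 942 simulated uncharacterized sequences they were 2.99%, 26.9% and 60.6%. The share of false calls was 5.00% for piRNAs, 10.2% for tRNA features, 2.15% for other RNA and 6.25% for uncharacterized sequences. The shares for tRNA features and uncharacterized sequences lay above the nominal 5%. A single simulated data set was drawn per class, so this does not settle whether those tests exceed their rate. The alternatives were other scalings (DESeq2-type size factors, library totals, upper-quartile factors), DESeq2 1.42.0 and limma-voom as tests, no filter on low counts and a filter of at least 10 CPM in 3 libraries, read counts in place of UMIs, the replicate number as a block, and leaving out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for shares and plots. No 2 libraries of a group were identical, and each pair of libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 24.1 or more).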

Results

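The libraries measured small RNA in cells isolated from the urinary bladders of mice, 3 from Control animals given saline and 3 from animals given cyclophosphamide (CYP), a treatment used to induce cystitis. The study asked which microRNAs (miRNAs, short RNAs that repress matching mRNAs) differ in the bladder cells of the treated mice. Each library held between 14900120 and 19442420 reads. The counts of miRNAs alone came to between 9110719 and 12180739 UMIs per library, and miR-143-3p, a miRNA abundant in smooth muscle, took from 21.8% to 25.4% of them.

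The miR-34 and miR-449 family, whose miR-34 members are transcribed under p53, held the 3 largest increases among the called miRNAs. miR-34c-5p rose 6.15-fold, from 88.0 ± 5.81 CPM in Control to 541 ± 127 CPM in CYP (SD, n = 3 each). Its partner from the same hairpin, miR-34c-3p, rose 6.71-fold, miR-34b-5p 6.04-fold and miR-34b-3p 5.46-fold. miR-34a-5p, the most abundant member, rose 2.49-fold, from 1513 ± 120.0 to 3770 ± 439 CPM, and miR-449a-5p rose 3.20-fold, from 26.4 ± 4.18 to 84.6 ± 23.3 CPM. All 8 measured members of the family passed the test over all miRNAs, and all 8 also passed when adjusted over the list alone. The list's median log2 fold change was 2.06 and camera called it higher (adjusted p = 9.23e-12), though not with an estimated correlation (adjusted p = 0.267 with an estimated correlation). In edgeR's test the log2 fold change of miR-34c-5p was 2.62 ± 0.16 (adjusted p = 8.82e-06) and that of miR-34a-5p was 1.32 ± 0.10 (adjusted p = 1.01e-05), and all 3 CYP libraries lay above all 3 Control libraries for both. The Mir34b and Mir34c hairpins lie together on chromosome 9 (51103034 to 51103645 in mm10, minus strand), in an intron of Btg4 on the opposite strand. Mir34a lies on chromosome 4 (150068454 to 150068555) apart from other annotated genes, and Mir449a lies on chromosome 13 (113037534 to 113037624) in an intron of Cdc20b.

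miR-21 and the miR-132 and miR-212 cluster also rose. miR-21a-5p, a miRNA induced by STAT3 and AP-1 in inflamed and wounded tissue rose 1.73-fold, from 26705 ± 891 to 46067 ± 3216 CPM (SD, n = 3 each). miR-21a-3p, the other strand of its hairpin, rose 2.92-fold, from 48.2 ± 2.71 to 141 ± 1.78 CPM. Both measured arms of miR-21 passed, over all miRNAs and adjusted over the list alone, and with 2 tested members the list had no set test. miR-132-3p, a target of the transcription factor CREB, rose 2.85-fold from 67.9 ± 5.47 to 194 ± 23.0 CPM, and miR-212-3p from the same transcript rose 2.79-fold from 5.22 ± 0.416 to 14.5 ± 1.26 CPM. All 4 members of the miR-132 and miR-212 cluster passed over all miRNAs and adjusted over the list alone, with miR-132-5p 2.64-fold higher. Camera called that list higher (median log2 fold change 1.44, adjusted p = 2.07e-06), and the adjusted p = 0.267 with an estimated correlation. edgeR's adjusted p was 8.22e-05 for miR-21a-5p (log2 fold change 0.79 ± 0.08), 5.09e-06 for miR-21a-3p and 1.03e-05 for miR-132-3p. Mir21a overlaps an exon of Vmp1 on chromosome 11 (86584067 to 86584158), and Mir132 and Mir212 lie in an intron of 1700016P03Rik on the same chromosome (75173388 to 75173747).

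**Figure D1:**
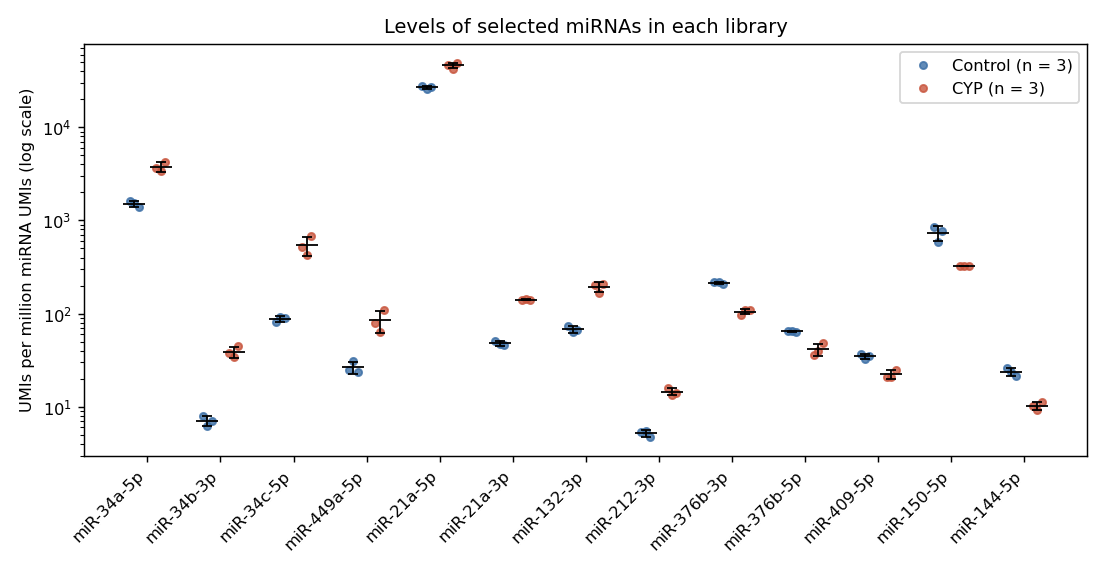
Level of 13 miRNAs in each library, in CPM on a log axis, with Control libraries in blue and CYP libraries in red (n = 3 each). Points are libraries, the black dash is the mean and the bar the SD. The CYP libraries of miR-34c-5p average 541 CPM against 88.0 in Control, and those of miR-150-5p 324 against 737.

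Other miRNAs with large increases were miR-672-5p, which rose 5.96-fold from 10.2 ± 1.95 to 60.8 ± 11.1 CPM (SD, n = 3 each), and miR-351-5p, which rose 2.09-fold from 207 ± 3.79 to 433 ± 10.4 CPM. miR-1983 rose 2.06-fold, from 10.1 ± 1.14 to 20.8 ± 3.59 CPM. Mir672 lies on chromosome X (104116175 to 104116274) in an intron of Nexmif. In edgeR's test the log2 fold changes were 2.58 ± 0.18 for miR-672-5p (adjusted p = 8.86e-06) and 1.06 ± 0.08 for miR-351-5p (adjusted p = 1.01e-05).

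The miRNAs with the largest decreases included miR-144-5p, miR-150-5p, miR-184-3p and miR-376b-3p of the Dlk1-Dio3 cluster. miR-144-5p, made in red cell precursors, was 2.33-fold lower in CYP, falling from 23.7 ± 2.31 to 10.2 ± 1.01 CPM (SD, n = 3 each). miR-150-5p, a miRNA of mature lymphocytes, was 2.28-fold lower, falling from 737 ± 139 to 324 ± 2.16 CPM. miR-184-3p was 2.26-fold lower (61.3 ± 6.26 to 27.2 ± 3.78 CPM) and miR-376b-3p was 2.04-fold lower (215 ± 5.20 to 105 ± 6.53 CPM). miR-129-5p, best known from brain, was 1.93-fold lower, and miR-146a-5p, an NF-kB-induced miRNA of immune cells, was 1.67-fold lower (483 ± 68.7 to 289 ± 31.2 CPM). miR-383-5p was 1.77-fold lower, miR-708-3p 1.63-fold and miR-485-5p 1.60-fold. In edgeR's test the log2 fold change of miR-150-5p was −1.19 ± 0.13 (adjusted p = 0.000139) and that of miR-376b-3p was −1.03 ± 0.09 (adjusted p = 3.55e-05), with all 3 CYP libraries below all 3 Control libraries for both. miR-144-3p was also called, with a log2 fold change of −1.14, but not without CYP replicate 1 (−1.03, adjusted p = 0.0537 by edgeR, range over its alternatives 7.90e-11 to 0.0537). Reads of miR-101c (log2 fold change −0.67 ± 0.16) cannot be told apart with certainty from those of its near-identical copy miR-101a-3p (−0.53 ± 0.08), so both are uncertain, and miR-101c lost its call with library totals (−0.55) and without Control replicates 2 or 3 (−0.72 and −0.59) or CYP replicates 1 or 2 (−0.55 and −0.59). miR-708-5p (−0.77 ± 0.19) lost its call with library totals (−0.65) and without Control replicates 1 or 3 (−0.78 and −0.65) or CYP replicates 1 or 2 (−0.70 and −0.63).

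Among the 885 miRNAs tested of 1277 listed, 109 were called by edgeR at an adjusted p below 0.05, 59 higher and 50 lower in CYP. Of these, 20 were at least 2-fold higher and 6 at least 2-fold lower. The groups did not overlap for any of the 109 called miRNAs, nor for 267 (30.2%) of all those tested, against 10% by chance. Without Control replicate 3 the count was 62 and without CYP replicate 1 it was 58. The split of higher to lower calls moved with the scaling: in edgeR it was 59 to 50 with TMM, 56 to 56 with RLE factors, which shift the median log2 fold change by −0.01, 78 to 29 with library totals, which shift it by 0.11, and 37 to 95 with upper-quartile factors, which shift it by −0.12. It was 57 to 79 in DESeq2, where the shift was also −0.01, so the scaling does not account for that split. None of the 109 changed sign in any of the 15 alternatives.

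**Figure D2:**
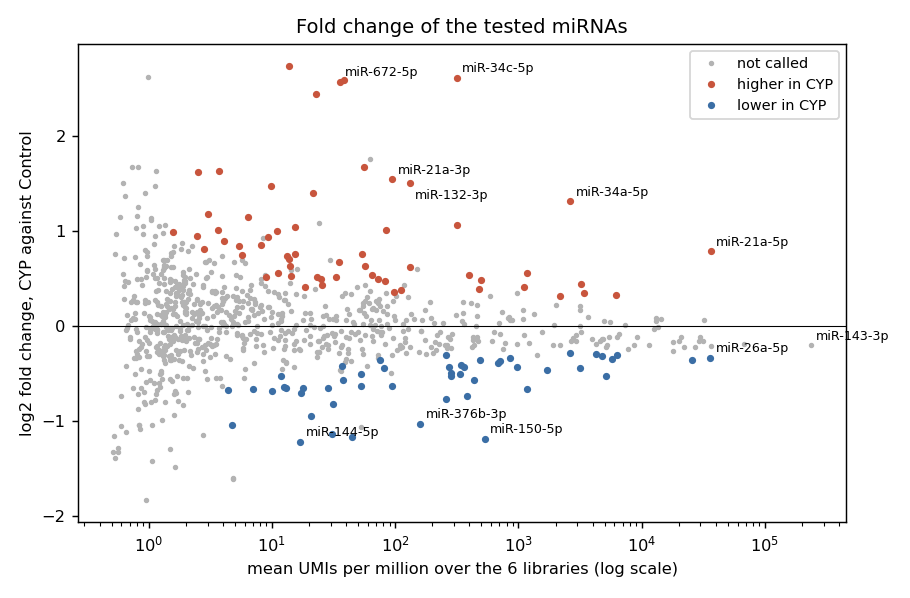
Log2 fold change of each of the 885 tested miRNAs in CYP against Control, by its mean level over the 6 libraries in CPM on a log axis. Grey points were not called, red points were called higher (59) and blue points lower (50) by edgeR at an adjusted p below 0.05.

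Most of the 10 most abundant miRNAs did not pass the test. miR-143-3p averaged 252809 ± 21208 CPM in Control and 219471 ± 18540 in CYP (SD, n = 3 each), miR-125b-5p 71479 ± 7287 and 62572 ± 2580, and miR-1a-3p, a striated muscle miRNA, 33042 ± 2521 and 29675 ± 1430. Their log2 fold changes were −0.20, −0.19 and −0.16. The members let-7c-5p, let-7a-5p and let-7f-5p gave −0.21, −0.15 and −0.11, miR-145a-5p −0.22 and miR-16-5p 0.06. Besides miR-21a-5p, 1 of the 10, miR-26a-5p, was called and fell 1.26-fold (40192 ± 2015 to 31927 ± 1759 CPM, edgeR adjusted p = 0.0173). That call was lost without Control replicate 3 (edgeR adjusted p = 0.0710) and without CYP replicate 1 (edgeR adjusted p = 0.0662), over a range of 4.60e-05 to 0.0710.

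The series text names 8 miRNAs, which answer its question most directly. Of these, miR-34c-5p, miR-34b-3p, miR-449a-5p, miR-21a-3p and miR-212-3p rose, and miR-376b-3p, miR-376b-5p (1.55-fold lower) and miR-409-5p (1.57-fold lower) fell. All 8 passed over all miRNAs and adjusted over the list alone, and all 8 were called in each of the 15 alternatives. The study chose this list on these samples, so its count is not independent evidence of its direction. Camera called the list higher (median log2 fold change 1.51, adjusted p = 0.0221). That call was lost with an estimated correlation (adjusted p = 0.362 with an estimated correlation) and with the filter of at least 10 CPM (camera adjusted p = 0.113), over a range of 0.00448 to 0.362.

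The Dlk1-Dio3 cluster, an imprinted domain whose miRNAs are expressed from the maternal chromosome, was lower in CYP as a group. Of its 80 tested members, 15 fell, none rose and 65 did not pass, and 61 of the 80 had a log2 fold change below 0. Adjusted over the list alone, 16 fell. miR-376b-3p fell most among the called members, miR-434-3p was 1.41-fold lower (331 ± 23.0 to 235 ± 9.88 CPM, SD, n = 3 each) and miR-127-3p was 1.35-fold lower (1115 ± 26.6 to 826 ± 24.2 CPM). The median log2 fold change was −0.23, against 0.02 over all miRNAs, and it stayed below 0 under the other scalings, at −0.25, −0.12 and −0.36 with RLE factors, library totals and upper-quartile factors. Camera called the list lower (adjusted p = 6.16e-08), and the adjusted p = 0.267 with an estimated correlation. The hairpins of the cluster lie on chromosome 12 between 109563692 and 109747960, with Mir127 and Mir434 opposite an exon of Rtl1 and Mir409 in an intron of Mirg. The fibroblast miRNAs, markers of another cell type, lay at a median of −0.22, and 14.1 ± 1.43% of the CYP reads were too short to be counted, against 9.96 ± 2.79% in Control.

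**Figure D3:**
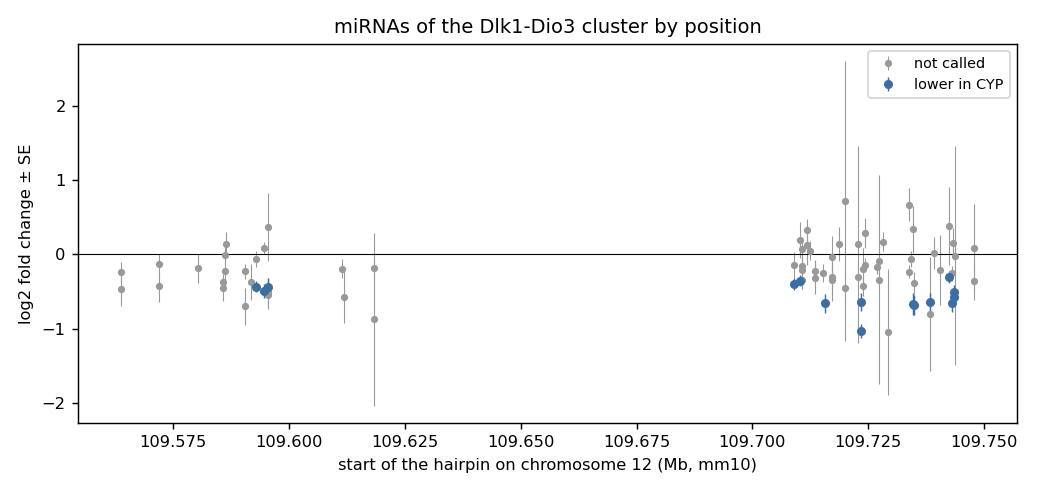
Log2 fold change with its SE of the miRNAs of the Dlk1-Dio3 cluster that have 1 annotated hairpin, by the start of the hairpin on chromosome 12 in mm10. Blue points were called lower in CYP by edgeR and grey points were not called. The members span 109563692 to 109747960.

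Camera called the erythroid, leukocyte and lymphoid lists lower in CYP with its preset correlation, and did not call the myeloid list. Of 9 erythroid miRNAs, 5 fell and 4 did not pass, with 6 falling when adjusted over the list alone. miR-144-5p is among them, as are miR-486b-5p (1.38-fold lower) and miR-486a-5p (1.42-fold lower), whose reads are uncertain because the sequences are near-identical. The erythroid list had a median log2 fold change of −0.47 (camera adjusted p = 0.000136, and adjusted p = 0.296 with an estimated correlation). Of 11 leukocyte miRNAs, 3 fell and 8 did not pass, and adjusted over the list alone 4 fell and 1 rose (median −0.29, and −0.16 without CYP replicate 2, camera adjusted p = 0.0161, and adjusted p = 0.275 with an estimated correlation). Of its 5 lymphoid members, 2 fell, miR-150-5p and miR-181a-5p, with 3 falling when adjusted over the list alone (median −0.30, camera adjusted p = 0.00843, and adjusted p = 0.296 with an estimated correlation). miR-181a-5p (log2 fold change −0.36 ± 0.09) was not called with library totals, or without Control replicate 3, CYP replicate 1 or CYP replicate 2 (−0.25, −0.32, −0.35 and −0.31). None of the 6 myeloid miRNAs passed, over all miRNAs or adjusted over the list alone, with miR-223-5p, a neutrophil and monocyte miRNA, at 0.43 ± 0.14 and miR-142a-3p, found in all blood lineages, at −0.31 ± 0.12 and called lower in 5 of its 15 alternatives. The myeloid list had no settled direction: its median was 0.25 (camera adjusted p = 0.713), −0.22 with the filter of at least 10 CPM and 0.03 without CYP replicate 3, where camera's direction turned to down. The leukocyte and lymphoid calls were lost with the filter of at least 10 CPM (camera adjusted p = 0.0779 for both, over ranges of 0.00209 to 0.275 and 0.00157 to 0.296).

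Of the other tissue lists, camera called the fibroblast list lower and the epithelial list higher. It also called the endothelial list lower, but that call was lost in 8 of 12 alternatives, among them an estimated correlation (camera adjusted p = 0.368). Of 11 fibroblast miRNAs, 4 fell and 7 did not pass, with 6 falling when adjusted over the list alone (median −0.22, camera adjusted p = 0.00416, and adjusted p = 0.296 with an estimated correlation). The miR-29 family, which represses collagen mRNAs, holds 2 of the 4: miR-29a-3p fell 1.28-fold (28737 ± 930.1 to 22462 ± 1677 CPM, SD, n = 3 each) and miR-29c-3p 1.24-fold. Of the 3 members of that family 2 fell, and 3 when adjusted over the list alone (median −0.31, camera adjusted p = 0.00939, and adjusted p = 0.296 with an estimated correlation). miR-29a-3p was not called without CYP replicate 1 (log2 fold change −0.36, edgeR adjusted p = 0.0616, range over its alternatives 7.37e-05 to 0.0616), and miR-29c-3p was called in 8 of its 15 alternatives, being lost without Control replicates 1 or 3 (−0.28 and −0.32) or CYP replicates 1 or 3 (−0.29 and −0.28). Both of these lists lost their call with the filter of at least 10 CPM, where the fibroblast median was −0.15 (camera adjusted p = 0.0779, ranges 0.00157 to 0.296 and 0.00155 to 0.296). Of 15 epithelial miRNAs, 3 rose, 1 fell and 11 did not pass, and adjusted over the list alone 5 rose and 1 fell (median 0.15, camera adjusted p = 0.0221, and adjusted p = 0.467 with an estimated correlation). miR-183-5p rose 1.33-fold and miR-429-3p of the miR-200 family 1.28-fold, while miR-203-3p, a miRNA of stratified epithelium, fell 1.28-fold.

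The epithelial list was not called without Control replicate 3 or CYP replicate 1 (camera adjusted p = 0.0892 and 0.162), nor by fry (adjusted p = 0.108), over a range of 0.00209 to 0.467, and its median was 0.26 with the filter of at least 10 CPM and 0.02 with upper-quartile factors. miR-183-5p and miR-429-3p were each not called with upper-quartile factors (log2 fold changes 0.30 and 0.23), without Control replicate 3 (0.37 and 0.35) or without CYP replicate 1 (0.35 and 0.28), and miR-203-3p was not called with library totals (−0.24) or without Control replicate 2 (−0.28). Of the 4 endothelial miRNAs 1 fell, miR-126b-5p, also when adjusted over the list alone, and that call was lost in 7 of its 15 alternatives, among them without any of Control replicates 1, 2 and 3 (−0.35, −0.35 and −0.36) or CYP replicates 1 and 2 (−0.33 and −0.35). For the list the median was −0.16 (camera adjusted p = 0.0403). Mir126b lies on the opposite strand within Mir126a, miR-126a-3p gave −0.11 in the same comparison and 0.00 with library totals, and the list was also not called without Control replicate 1 (adjusted p = 0.105), Control replicate 3 (0.0892), CYP replicate 1 (0.0562) or CYP replicate 3 (0.0635), over a range of 0.0137 to 0.368 in camera and fry. None of 13 muscle miRNAs passed, over all miRNAs or adjusted over the list alone (median −0.16, mean 0.04, camera direction down, adjusted p = 0.114). Without CYP replicate 3 camera called the muscle list lower (adjusted p = 0.0170, range 0.0170 to 0.543). miR-133a-3p of striated muscle gave −0.25 ± 0.10. None of the 4 miR-143 and miR-145 members passed, either way of adjusting (median −0.20, camera adjusted p = 0.0683). That list gained a call in 3 of its 12 alternatives. Among these, it was called lower without Control replicate 2 or CYP replicate 3 (camera adjusted p = 0.0402 and 0.0112, range 0.0112 to 0.329). Of 8 neuronal miRNAs 1 fell, miR-129-5p, also adjusted over the list alone (median −0.19, and −0.09 without Control replicate 1, camera adjusted p = 0.260), and none of 5 liver and kidney miRNAs passed either way (median −0.20, camera adjusted p = 0.114), with miR-194-5p at −0.20 ± 0.08.

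The list of proliferation clusters, which holds miR-17-92 and related clusters that MYC and E2F induce, was called higher in CYP by camera. Of 18 members, 5 rose and 13 did not pass, and adjusted over the list alone 6 rose and 1 fell. miR-93-5p rose 1.35-fold (2756 to 3734 CPM, n = 3 each) and miR-18a-5p 1.69-fold (11.5 to 19.5 CPM). In the cluster tests added after the data were seen, camera called Mir25/93/106b higher (4 of 6 rose, adjusted p = 0.00130). The miR-17-92 cluster itself was not called (1 of 8 rose, camera adjusted p = 0.193). Nor was the cluster of Mir106a, Mir18b, Mir20b and Mir363 (0 of 5 rose, camera adjusted p = 0.596). The list's median log2 fold change was 0.29 (camera adjusted p = 0.00939, and adjusted p = 0.296 with an estimated correlation). It was 0.10 without CYP replicate 3, 0.16 with upper-quartile factors and 0.40 with library totals. Of 10 inflammation-induced miRNAs, 4 rose, among them miR-132-3p and miR-21a-5p, 1 fell, miR-146a-5p, and 5 did not pass, with 4 rising and 2 falling when adjusted over the list alone (median 0.23, and 0.07 without CYP replicate 3, camera adjusted p = 0.114). Of 12 p53-linked miRNAs, the 3 of the miR-34 family rose and 9 did not pass, also adjusted over the list alone. Their median log2 fold change was −0.05, while their mean was 0.41 and camera's direction up (adjusted p = 0.509), and the median was 0.06 with library totals, 0.09 with the filter of at least 10 CPM, −0.02 without Control replicate 1 and −0.11 without CYP replicate 1. fry called the p53-linked, inflammation-induced, and liver and kidney lists (fry adjusted p = 0.00627, 0.0115 and 0.0115).

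In the miR-15/16 family 2 of 6 members rose, 1 fell and 3 did not pass, the same counts as adjusted over the list alone (median 0.05, −0.07 with upper-quartile factors, 0.07 without Control replicate 1 and 0.03 without Control replicate 2, camera adjusted p = 0.392). miR-322-5p rose 1.47-fold and miR-15b-5p 1.40-fold. miR-15b-5p was not called without Control replicate 3 (log2 fold change 0.47) or CYP replicate 1 (0.46). None of 9 let-7 members passed either way (median −0.11, and −0.06 without CYP replicate 3, camera adjusted p = 0.168), and without CYP replicate 1 camera called that list lower (adjusted p = 0.0395, range 0.0395 to 0.717). Neither arm of miR-210, the hypoxia-induced miRNA, passed over all miRNAs or adjusted over the list alone (log2 fold changes 0.16 and 0.74). Camera called 12 of the 21 lists in all, 5 higher and 7 lower, fry called 13, and with an estimated correlation none was called.

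**Figure D4:**
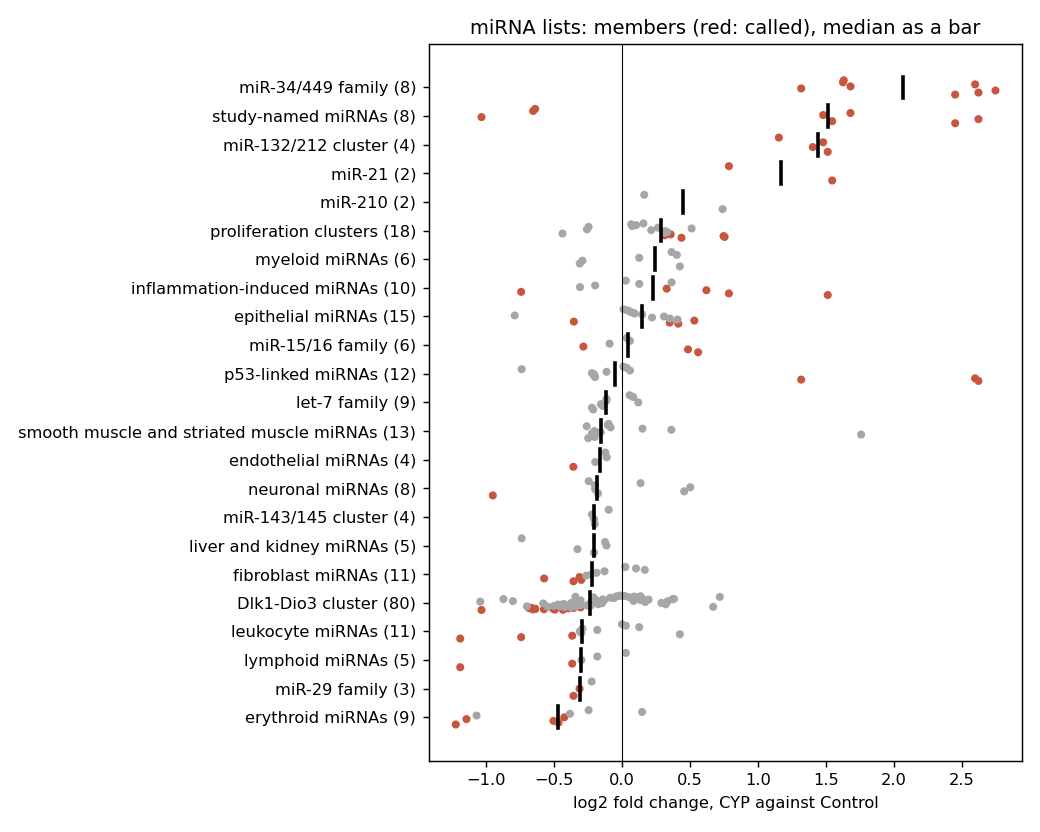
Log2 fold changes in CYP against Control of the members of each of the 23 lists, with the number of tested members in brackets. Red points were called by edgeR and grey points were not, and the black bar is the list's median, from 2.06 for the miR-34 and miR-449 family to −0.47 for the erythroid list.

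No piRNA, tRNA or other RNA feature was called by edgeR with the default filter, TMM scaling, UMI counts and all 6 libraries. In the table of piRNAs 0 of 165 tested features were called, against 50 at an unadjusted p below 0.05 (11 higher, 39 lower), and limma-voom also called 0. DESeq2 called 39 (4 higher, 35 lower), library totals 46 (41 higher, 5 lower, with the median log2 fold change shifted by 0.54), upper-quartile factors 4, and edgeR without Control replicate 1 called 35. The feature with the smallest p among those lower, the copy of piR_000691 at position 126455417 of chromosome 8, gave a log2 fold change of −1.69 ± 0.33 with an adjusted p of 0.104 in edgeR. The 26 tested copies of that piRNA on chromosome 8 gave −1.69 to −0.09, and reads can be split between copies, so these values are uncertain. Control replicate 1 stood apart in this table, with 30337 UMIs and a TMM factor of 0.606 against up to 1.25 elsewhere.

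Of 369 tRNA features 0 were called by edgeR, against 80 at an unadjusted p below 0.05 (21 higher, 59 lower), and limma-voom called 0. The mitochondrial tRNA mt-Th (histidine) averaged 1534 ± 165 CPM in Control and 757 ± 36.6 in CYP (SD, n = 3 each), a log2 fold change of −1.02 ± 0.19 with an adjusted p of 0.115 in edgeR. tRNA-Gly-CCC-5-1 averaged 8718 ± 3359 and 1862 ± 465 CPM (log2 fold change −2.23 ± 0.43), and tRNA-Leu-CAG-1-1 averaged 1045 ± 43.5 and 1761 ± 325 CPM (0.75 ± 0.21). Reads of tRNA genes with the same anticodon can be split between near-identical copies, so these values are uncertain. DESeq2 called 72 features (12 higher, 60 lower), and edgeR called 45 without Control replicate 1 and 64 without Control replicate 3. The CPM values above are scaled by TMM factors that ran from 0.346 in Control replicate 1 to 1.80 in CYP replicate 3. With library totals alone the median log2 fold change shifted by 0.91. The level and direction of a tRNA feature therefore hold only relative to the others.

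Of 679 other RNA features 0 were called by edgeR (smallest adjusted p = 0.0703), against 84 at an unadjusted p below 0.05 (24 higher, 60 lower), and limma-voom called 0. The nuclear RNA Malat1 averaged 339 CPM in Control and 566 in CYP (n = 3 each), a log2 fold change of 0.74 ± 0.20 (SE). The snoRNA AF357425 averaged 370 ± 57.6 and 178 ± 7.16 CPM (−1.05 ± 0.20), and the snoRNA Gm22962 33.3 ± 5.28 and 10.9 ± 2.36 CPM (−1.59 ± 0.27). These 2 snoRNAs differ at 4 of 73 bases, so reads can be split between them and both values are uncertain. DESeq2 called 14, library totals 3 (with a median shift of −0.17), the fit without a count filter 4, and edgeR without Control replicate 1 called 17.

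Fragments of tRNA held 9.71 ± 4.81% of the characterised reads in Control and 5.49 ± 0.646% in CYP (SD, n = 3 each, exact permutation p = 0.2). The difference was −4.23 percentage points, and −1.57 without Control replicate 1, where the share was 15.0%. Fragments of other RNA held 8.01 ± 2.09% and 11.7 ± 0.708%, those of mRNA 0.151 ± 0.0156% and 0.242 ± 0.0106%, and miRNA hairpins 0.0461 ± 0.00848% and 0.0759 ± 0.00116%, each with no overlap between the groups (exact permutation p = 0.1, n = 3 each). That is the smallest p possible with 3 against 3 libraries, so no class could pass 0.05, and adjusted over the 7 classes the exact p was 0.233. miRNAs held 81.5 ± 2.54% and 81.7 ± 1.45% (exact permutation p = 0.9, n = 3 each), as a share of all reads 67.8 ± 1.30% and 64.2 ± 1.12%. The rRNA class held 0.259 ± 0.122% and 0.400 ± 0.0658% and piRNAs 0.319 ± 0.0967% and 0.383 ± 0.0298% (exact permutation p = 0.2 and 0.5, n = 3 each). The rRNA class leaves out the 45S ribosomal precursor, which was counted under other RNA. That precursor took 58.4% to 63.1% of the other RNA UMIs in the Control libraries and 65.2% to 66.2% in the CYP libraries. Other RNA was therefore mostly ribosomal, and the rRNA class is not the whole ribosomal share.

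**Figure D5:**
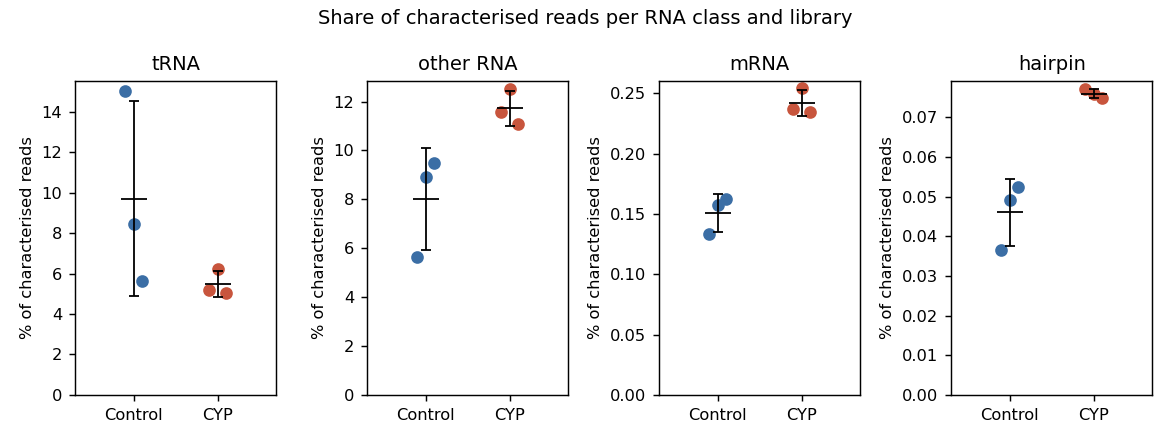
Share of characterised reads held by tRNA, other RNA, mRNA and miRNA hairpin fragments in each library, in percent on axes that start at 0. Points are libraries, the black dash is the mean and the bar the SD (n = 3 per group). Control replicate 1 holds 15.0% tRNA, and the 3 CYP libraries lie between 5.03% and 6.23%.

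The authors' deposited table gives fold changes for the same libraries. In the authors' deposited table, 157 miRNAs have an unadjusted p below 0.05, 48 higher and 109 lower in CYP, and 11 are at least 2-fold higher and 5 at least 2-fold lower. The authors' deposited table lists miR-34c-5p at 5.34-fold, miR-34b-3p at 4.29-fold, miR-449a-5p at 2.69-fold and miR-376b-3p at 0.48-fold. Across the 885 miRNAs tested here, which are not independent replicates, the sign was the same for 92.7% and the log2 fold changes had a Pearson correlation of 0.864 and a Spearman correlation of 0.949 with the authors' deposited table. Over the 381 miRNAs at 10 CPM or more in 3 libraries the Pearson correlation was 0.993. All 109 miRNAs called here have the same sign in the authors' deposited table, and 91 of them have a p below 0.05 there. Of the 26 called miRNAs changed at least 2-fold here, 25 have a smaller change in the authors' deposited table.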

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

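The tests of the Dlk1-Dio3, blood cell and tRNA patterns and those of uncharacterized sequences and genomic clusters were chosen after a first look at the results, and only the counts over other splits were planned before those counts were seen, though after the count for the real groups. Reads that mapped to the genome but to no class of RNA were looked at because they lie outside the main measurement. Among 942 such sequences tested, 5 were higher and 8 lower in CYP by edgeR, though several of these differ from each other only at an end. The count was 26 without Control replicate 1, 0 without Control replicate 2, 1 without Control replicate 3, 0 without CYP replicate 1 or CYP replicate 2, and 3 without CYP replicate 3. Such sequences took 1.13 ± 0.0400% of all CYP reads against 0.918 ± 0.0969% in Control (SD, n = 3 each, exact permutation p = 0.1). Reads too short to be counted took 14.1 ± 1.43% in CYP against 9.96 ± 2.79% in Control (SD, n = 3 each, exact permutation p = 0.1), with no overlap.

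The first pattern weighed is the fall of the Dlk1-Dio3 cluster. Whether a few abundant members carry the fall was not decided by a test. Each of the 80 tested members counts equally in the cluster's median of −0.23, whatever its level. That a few members cannot set this median holds by its construction and is not evidence. The share of 76.2% below 0 decides nothing by itself, since a median below 0 already put at least 50% there. Some scarce called members fell, with log2 fold changes of −0.67 for miR-668-3p (mean 7.04 CPM) and −0.66 for miR-1193-3p (12.9 CPM). Other scarce members, not called, lay above 0, such as miR-382-3p at 0.67 (4.9 CPM) and miR-380-5p at 0.32 (6.25 CPM). The abundant miR-127-3p (970 CPM) gave −0.43 and miR-379-5p (676 CPM) −0.39. Of the 80 members, 65 did not pass and 19 lay above 0. Fewer mesenchymal cells in the CYP preparations stays open: the fibroblast miRNAs outside the cluster lay 0.0103 above the cluster's median (log2, bootstrap SE 0.0906). Lists of other tissues had medians near it too, at −0.20 for liver and kidney, −0.19 for neuronal and −0.16 for endothelial miRNAs. The epithelial list lay at 0.15 and the erythroid list at −0.47. The match is therefore not particular to mesenchymal cells and decides nothing. Lower transcription of the imprinted domain also stays open, and was not tested apart from a change in cell types.

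The second pattern is the fall of blood cell miRNAs. Fewer leukocytes of every kind stays open: miR-142a-3p lay 0.88 (SE 0.18) above miR-150-5p on the log2 scale, but miR-150-5p was among the falls that drew attention to the pattern, so the gap decides nothing, and miR-142a-3p itself gave −0.31 and did not pass (edgeR adjusted p = 0.162). Less whole blood left in the CYP bladders stays open for the same reason: miR-223-3p lay 1.20 (SE 0.34) above miR-451a, a red cell miRNA of the same pattern, not called itself (edgeR adjusted p = 0.0962).

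The third pattern is the larger share of tRNA fragments in Control. Whether Control replicate 1 alone accounts for it stays open: of the other Control libraries, 1 share, 5.64%, lay inside the CYP range of 5.03% to 6.23%, and the other, 8.48%, lay above it, with a difference of −1.57 points without Control replicate 1. General RNA breakdown in Control replicate 1 is argued against by its rRNA share of 0.123%, below that of the other 5 libraries. That class leaves out the 45S ribosomal precursor, counted under other RNA. Other RNA held 5.62% of the characterised reads of that library, and 45S took 58.4% of its other RNA UMIs. Both values also lay below those of the other 5 libraries. All of these are shares, which a large tRNA share also lowers. A difference in how that library was made or in its animal stays open.

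With 3 libraries per group there are 10 splits, too few for a share under 0.05. The real split gave 109 called miRNAs and the highest other split 0, and 1 split of the 10 gave as many. For piRNAs, tRNA features and other RNA features the real split and the highest other split both gave 0, so 10 of the 10 splits gave as many. For the lists the real split gave 12 and the highest other 6, for the uncharacterized sequences 13 and 0, and for the genomic clusters 10 and 7, so that 1 of 10 gave as many for each.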

How the results depend on the processing

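The tests of clusters and uncharacterized sequences were chosen after the data were seen. Of 1105 values of single miRNAs under the alternatives, 1007 kept their direction and side of the threshold, 66 lost and 28 gained a call, and 4 changed sign. Of 251 values of single lists, 214 kept both, 27 lost and 8 gained a call, and 2 changed camera's direction, which need not be the sign of the median. The changed signs of single miRNAs were those of miR-126a-3p with library totals (0.0004), miR-16-5p with upper-quartile factors (−0.054) and over left-out libraries (−0.0028 without CYP replicate 1 to 0.1712 without CYP replicate 3), mmu-let-7f-5p over the same left-out libraries (−0.1712 to 0.0043). List medians changed sign for the myeloid miRNAs with the filter of 10 CPM (−0.222), the p53-linked miRNAs with that filter (0.0870) and with library totals (0.0599), and the miR-15 and miR-16 family with upper-quartile factors (−0.0744). Without CYP replicate 3 only camera's direction turned for the myeloid list, whose medians over left-out libraries were 0.0262 to 0.309. Called miRNAs numbered 58 to 139 over left-out libraries, 30 to 67 higher and 28 to 72 lower. Higher ones came to 37 with upper-quartile factors, and lower ones to 95 there, 29 with library totals and 79 in DESeq2, where 258 adjusted p-values were missing. piRNA calls came to 46 with library totals, 4 with upper-quartile factors, 39 in DESeq2 and 0 to 35 over left-out libraries. tRNA calls came to 72 in DESeq2 and 0 to 64 over left-out libraries, other RNA calls to 3 with library totals, 14 in DESeq2, 4 with no filter and 0 to 17 over left-out libraries. Uncharacterized calls came to 5 with upper-quartile factors, 42 in DESeq2, 24 with the replicate block and 0 to 26 over left-out libraries. List calls came to 0 with an estimated correlation and 6 with the filter of 10 CPM, and cluster calls to 0 with an estimated correlation. The miRNA share of characterised reads, 0.184 points higher in CYP, turned lower without CYP replicate 1 (−0.0646), CYP replicate 3 (−0.381) or Control replicate 1 (−1.14) and as a share of all reads (−3.60), the piRNA and rRNA differences came to 0.00774 and 0.0739 without Control replicate 1, and the correlation with the authors' table at 10 CPM was 0.993. Deviations from the group mean, not whole profiles, correlated at −0.33 to 0.05 between libraries with the same replicate number. By that measure 0 of 6 libraries correlated best with their own number, so they were not treated as pairs. With so few libraries this check cannot exclude a pairing. With the replicate block 142 miRNAs were called. For all of these the cause was not tested.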

Other observations

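The tests of clusters and of uncharacterized sequences below were all chosen after the results were seen. In the X chromosome cluster of Mir322, Mir351, Mir503, Mir542 and Mir450b (53047997 to 53054349 in mm10), whose miR-322 and miR-503 slow the cell cycle and promote muscle differentiation, 8 of 10 tested miRNAs rose. miR-351-5p rose 2.09-fold, miR-503-5p 2.02-fold (56.1 ± 1.71 to 114 ± 12.2 CPM, SD, n = 3 each), miR-450b-5p 1.80-fold and miR-322-5p 1.47-fold. Camera called the cluster higher (median log2 fold change 0.54, adjusted p = 3.36e-07, and adjusted p = 0.310 with an estimated correlation). In the Mir25/93/106b cluster on chromosome 5, hosted by a gene that MYC and E2F drive, 4 of 6 rose, in Mir182/96/183 on chromosome 6 2 of 5, in Mir15b/16-2 on chromosome 3 2 of 3 (miR-15b-3p 1.69-fold) and in Mir130b/301b on chromosome 16 2 of 3 (miR-130b-3p 1.92-fold, miR-301b-3p 1.76-fold). In Mir144/451a on chromosome 11, 2 of 3 fell, and in the 2 called parts of the Dlk1-Dio3 domain 12 of 55 and 3 of 19 fell. Camera did not call the part with Mir341, Mir1188 and Mir370 (0 of 4 fell, adjusted p = 0.234). It also did not call the part on the minus strand with Mir3544 and Mir3071 (0 of 3 fell, adjusted p = 0.952). Of 40 clusters camera called 10, 7 higher and 3 lower, with the Mir34b/c and Mir132 and Mir212 clusters among them, and none with an estimated correlation.

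Small RNA reads from other RNAs of the Dlk1-Dio3 domain, snoRNAs among them, were read for the same direction. Such reads do not measure the level of whole transcripts. Of 13 other RNA features there, 12 had a log2 fold change below 0, against 351 of all 679, with a median of −0.69. The snoRNA AF357425, uncertain because of its near-identical copy Gm22962, gave a log2 fold change of −1.05 ± 0.20, and 1 transcript of Rian, a maternally expressed RNA of the domain, averaged 23.2 ± 2.92 CPM in Control and 11.5 ± 1.97 in CYP (SD, n = 3 each). Neither passed (edgeR adjusted p = 0.0703 and 0.233). The 13 overlap in part, since several are transcripts of Rian or Mirg and the named Rian transcript spans AF357425, so they are not 13 independent values. Exons of Mirg also hold hairpins of the cluster, among them Mir382 and Mir485, so reads of Mirg may be pieces of the same miRNA precursors.

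Among the uncharacterized sequences called by edgeR, 3 are placed at position 86584141 of chromosome 11, where Mir21a and Vmp1 both lie. All 3 end in the same 17 bases and differ only in how early they start, so they are not separate findings. The sequence of 17 bases, which rose 2.34-fold, matched the annotated Mir21a and Vmp1 transcripts. Those of 18 and 20 bases, which rose 2.46 and 3.69-fold, matched Vmp1 alone over their full length. Their extra bases lie outside the annotated Mir21a hairpin, so that match does not show that they come from Vmp1 mRNA. A sequence at position 71585761 of chromosome 9, inside Myzap, rose 14.5-fold, from 32.2 ± 29.9 to 452 ± 196 CPM (SD, n = 3 each). At position 11575 of the mitochondrial genome, inside mt-Th, 4 sequences were 2.02 to 2.18-fold lower. These 4 differ only in their last bases, so they are not separate findings either. Another sequence, at position 16156, was 1.94-fold lower. Most of the 13 calls were lost when single libraries were left out: 0 of them remained without Control replicate 2, CYP replicate 1 or CYP replicate 2, 1 without Control replicate 3 and 3 without CYP replicate 3, while 12 were among the 26 calls without Control replicate 1. All 13 kept their sign without any 1 library, and the sequence in Myzap ranged from 8.52 to 24.6-fold. That sequence was called in 9 of 15 alternatives, and it was the only 1 of the 13 not called by limma-voom (adjusted p = 0.496).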
